A study of Rattus norvegicus with 26 samples.

How the data were processed

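The study measured gene expression in primary hepatocytes of female Sprague Dawley rats on 1 type of short-oligonucleotide array, a commercial rat array with 8799 probe sets. Cultures from 2 pools of 3 animals each were treated for 48 hours with TCDD, PCB 126 or 0.5% DMSO, and 26 arrays were made, 11 of pool 1 and 15 of pool 2. The values used here are the authors' deposited log2 expression values, from -1.43 to 15.01, 1 table column per array. The summary was made with GCRMA 2.8.0, and RMA is also named, per the submitters' processing notes. The settings of that step and the role of RMA are not given in the sources used here. Scanner files were not used here, so the background correction, normalization and probe summary could not be repeated with other settings. GCRMA estimates background from probe sequence, normalizes between arrays and sets low signals close together, so differences between dim values are compressed and differences of bright values are on a log2 scale of relative signal.

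Groups were taken from the labels, which give the chemical, the log10 molar dose and the pool of each array. This gave 15 groups, the vehicle and 7 doses of each chemical, of 2 arrays (1 per pool) or 1 array (pool 2). Every column of the table belonged to a sample, with 0 columns left over. No 2 arrays were identical. The closest pair had r = 0.997 and a largest difference of 1.40 log2. Pool was treated as a block because the labels place arrays of 1 pool in the same animals' cells. In the 11 groups with an array of each pool, deviations from the group means were correlated between groups. For arrays of the same pool r ran from 0.461 to 0.892 (mean 0.732). Any shift between the pools gives such correlations, so they do not show that arrays share animals. Array medians were 3.85 ± 0.08 (SD, n = 11) in pool 1 and 3.58 ± 0.07 (SD, n = 15) in pool 2. Each pool is 1 biological unit of mixed cells, and nothing says that arrays within a pool came from separate animals, so p values measure the spread between arrays.

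Control probe sets (59) were left out, and of 8740 others 5197 were kept whose second-highest value over the arrays was above the median of all values, 3.71 log2. Gene symbols came from a table of the platform's probe sets: 7006 probe sets have 1 symbol, 308 name several genes and 1426 are not listed with a gene. Of the 7006, the Entrez identifiers of 6985 matched a current rat gene table, and 0 symbols needed an update. The kept probe sets with 1 gene, 4195, represent 3034 genes, each represented by its probe set with the highest mean. Probe sets whose names end in _s or _f can share sequence between related genes, such as members of the Cyp2c, Ugt and Sult families and Cyp1a1, and their gene assignment is less certain. Of the AhR battery, Ugt1a6 (12 probe sets) and Gsta2 (2) occur only on probe sets that name several genes, and no probe set listed Tiparp or Ahrr, so these members were not analysed here. No genome was used.

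The tests were made with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust), on the log2 values without a pseudocount, with Benjamini-Hochberg adjusted p below 0.05 within each comparison over the 5197 probe sets. A trend model over all 26 arrays had the pool, the chemical and a slope on log10 dose within each chemical, so each slope is fitted within the 12 arrays of its chemical, and the 2 vehicle arrays and the other chemical enter through the shared pool term and the spread. It had 20 residual degrees of freedom and a median prior of 4.65. A second model had the pool and 15 groups, with 10 residual degrees of freedom, and gave the contrasts of each dose with vehicle, of the mean of the 2 highest doses with vehicle, of TCDD with PCB 126 at the doses -12, -10 and -8 and of the 2 high-dose means. All groups share 1 estimate of the spread, and a group of 1 array is assumed to vary like the others. A further model had slopes by pool. These models, the filter, the rule for named genes and the gene lists were fixed before the data were examined.

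Named genes follow a rule: per trend and high-dose comparison the 10 genes with the largest positive and the 10 with the largest negative estimate among those called with the same sign in both pools, per matched-dose contrast the same, all measured members of the AhR battery, and per gene list up to 4 members with the smallest p. Probe sets that name several genes or none were not named. The 27 gene lists were the AhR battery, CAR and PXR targets, constitutive liver P450s, bile acid synthesis and transport, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPARa targets, glucose production and handling, amino acid breakdown and urea cycle, NRF2 and glutathione, retinoid handling, steroid and growth hormone axis, UDP-glucuronosyltransferases and sulfotransferases, acute phase and complement, hepatocyte secreted and identity genes, cytoskeleton and dedifferentiation, cell cycle, ER stress and integrated stress response, heat shock, p53 and apoptosis, ribosomal proteins, mitochondrial respiration, clock genes, and markers of macrophages and Kupffer cells, endothelial cells, stellate cells and fibroblasts, and cholangiocytes. They were tested with camera at a preset correlation of 0.01 between genes, again with the correlation estimated, and with fry, whose first p tests whether a list's genes move on balance one way and whose mixed p whether they change in either direction. Lists overlap in part, and hepatocytes also express some genes of the marker lists.

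Relative potency was the EC50 of TCDD divided by the EC50 of PCB 126 from least-squares log-logistic curves, with a baseline per pool, a maximum and an EC50 per chemical and 1 Hill slope, fitted by a grid search in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3. The grid had steps of 0.05 in log10 EC50 and reached 1 decade beyond the tested doses, and 8 Hill slopes between 0.3 and 4 were tried. Intervals came from 1000 residual bootstrap draws. The median over genes used genes called in both trends with the same sign, a fitted change of at least 1 log2 for each chemical and EC50 values within the tested doses. Figures were drawn with Matplotlib 3.10.9.

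The comparisons, the list test and the curves were tested on simulated data. For the comparisons 200 of 5197 probe sets were changed. The list test used 3034 genes, with a list of 20 raised by 0.15 log2 per decade of TCDD dose, and the curves 200 draws per setting. For the TCDD and PCB 126 trends 99% of changes of 0.25 log2 per decade and 100% of those of 0.5 were recovered, with 10 and 7 false calls. The added trends were straight lines with no array standing apart. These shares therefore do not hold for responses that level off with dose, and a gene not called can have a steeper slope. For the high doses 83% (TCDD) and 76% (PCB 126) of 1 log2 changes were recovered, and 97% and 99% of 2 log2 changes. At the matched doses -8, -10 and -12, 67%, 66% and 67% of 1 log2 changes and 98%, 98% and 96% of 2 log2 changes were recovered, and for a dose with 1 array (TCDD -9) 51% and 90%. Camera found the raised list in 50 of 50 draws, with 0 false calls among 1000 lists left alone. The simulated genes varied independently, so this does not give the rate of false calls for lists of correlated genes. In the data the estimated correlation was 0.51 for the AhR battery and 0.19 for identity genes in the TCDD trend. The curves recovered the log10 relative potency with a median absolute error of 0.05 for a maximum of 6 log2 and a residual SD of 0.3, and of 1.125 for a maximum of 2 and a residual SD of 1.3. All simulated curves had the same true difference in potency, and chemicals of equal potency were not simulated.

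The results were also computed with no pool term, no filter, a stricter filter (above 5.71 log2, keeping 2711 probe sets), quantile normalization, centring of each array on its median, plain eBayes, 1 probe set per gene, leaving out each array or pool, other sets of doses and arrays in the fit, camera with ranks or the mean of a gene's probe sets, and other curve settings. Chosen after seeing the data were the removal of the array labelled PCB 126 -12 of pool 2, the removal of 3 arrays (that array, PCB 126 -5 of pool 2 and TCDD -11 of pool 2), curves on linear values, and median centring for the gene lists.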

Results

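The data were 26 oligonucleotide arrays of primary hepatocytes from female Sprague Dawley rats. The cells were cultured for 48 hours with TCDD, a chlorinated dibenzo-p-dioxin, with PCB 126, a coplanar chlorinated biphenyl, or with the vehicle, 0.5% DMSO. Both chemicals bind the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor, and the question of the study was how their dose responses compare. Hepatocytes came from 2 pools of 3 animals each, with 11 arrays of pool 1 and 15 of pool 2. Each pool had 1 vehicle array. TCDD was given at 0.01 pM, 1 pM, 0.1 nM, 10 nM and 316 nM (log10 M of -14, -12, -10, -8 and -6.5) in both pools, and at 10 pM and 1 nM (-11 and -9) in pool 2. PCB 126 was given at 1 pM, 0.1 nM, 10 nM, 1000 nM and 10000 nM (-12, -10, -8, -6 and -5) in both pools, and at 10 pM and 1 nM in pool 2. Each dose thus had 2 arrays, 1 per pool, or 1 array. A pool is 1 biological unit, and no dose had 2 arrays of 1 pool. In the model of dose groups the p values thus rest on how far the 2 pools disagreed in their dose effects. In the trend model the spread also holds departures from a straight line. The number of arrays limits the precision of every value. Errors written as ± are standard errors of the limma model unless SD is named.

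Cyp1a1, the P450 most used as a readout of AhR activation, had a mean log2 value of 3.36 ± 0.13 (SD, n = 2) in vehicle cultures. It reached 12.45 ± 0.11 (SD, n = 2) with 10 nM TCDD and 12.31 ± 0.44 (SD, n = 2) with 10 nM PCB 126. At 1 pM its value was 9.39 ± 0.03 (SD, n = 2) with TCDD. With 1 pM PCB 126 it was 3.21 in pool 1 and 10.80 in pool 2, against 7.91 at the next higher dose, 10 pM, in pool 2. The array labelled PCB 126 -12 of pool 2 therefore stood apart from its neighbours, and values without it are given where a named gene's call or a count of calls depends on it. Cyp1a2, Cyp1b1 and Aldh3a1 stood out on the same array, with means and SDs over both pools of 6.60 ± 3.69, 6.65 ± 3.52 and 4.34 ± 2.97 (n = 2 each).

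**Figure D1:**
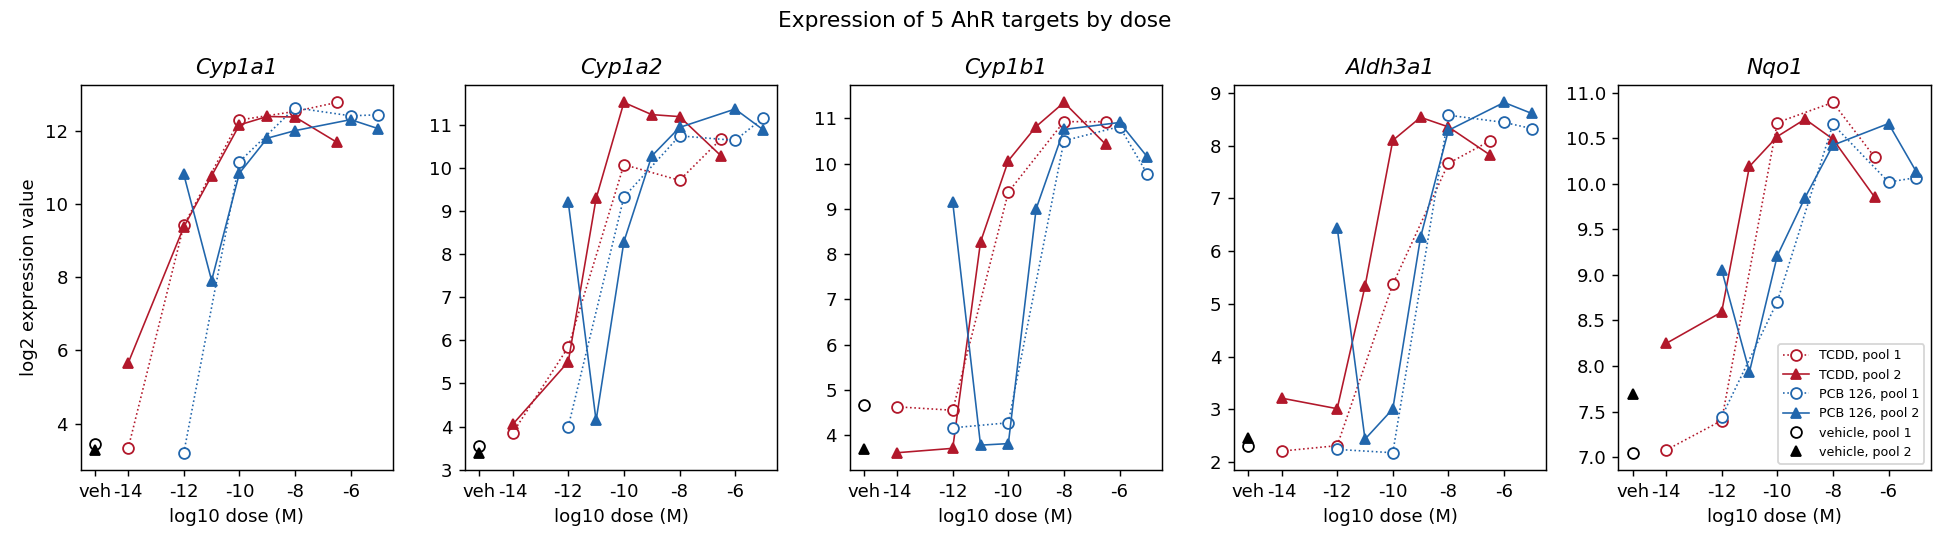
Log2 value of 5 AhR target genes (vertical axes) against log10 dose in M (horizontal axes, vehicle at the left), with 1 point per array, TCDD in red, PCB 126 in blue, pool 1 as open circles with dotted lines and pool 2 as filled triangles with solid lines. Cyp1a1 lies near 3.36 in vehicle cultures and near 12.45 at 10 nM TCDD, and the pool 2 point of PCB 126 at -12 lies at 10.80.

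Across all probe sets the first principal component held 56.2% of the variance and separated the pools, and the second held 17.3% and followed dose. The pools differed at 4145 of 5197 probe sets (79.8%), of which 2080 were higher in pool 2 and 2065 lower, by limma with chemical and dose in the model. With each array centred on its median, 2959 were higher and 1409 lower, and the median difference over all probe sets moved from 0.02 to 0.30 log2. Measures of array quality also differed between pools: the actin 3' minus 5' difference averaged 0.82 ± 0.12 log2 (SD, n = 11) in pool 1 and 1.51 ± 0.22 (SD, n = 15) in pool 2. The mean reverse-strand control signal was 7.71 ± 1.04 (SD) and 5.80 ± 0.94 (SD). Pool and these measures cannot be told apart, and the pool was a term in every comparison.

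**Figure D2:**
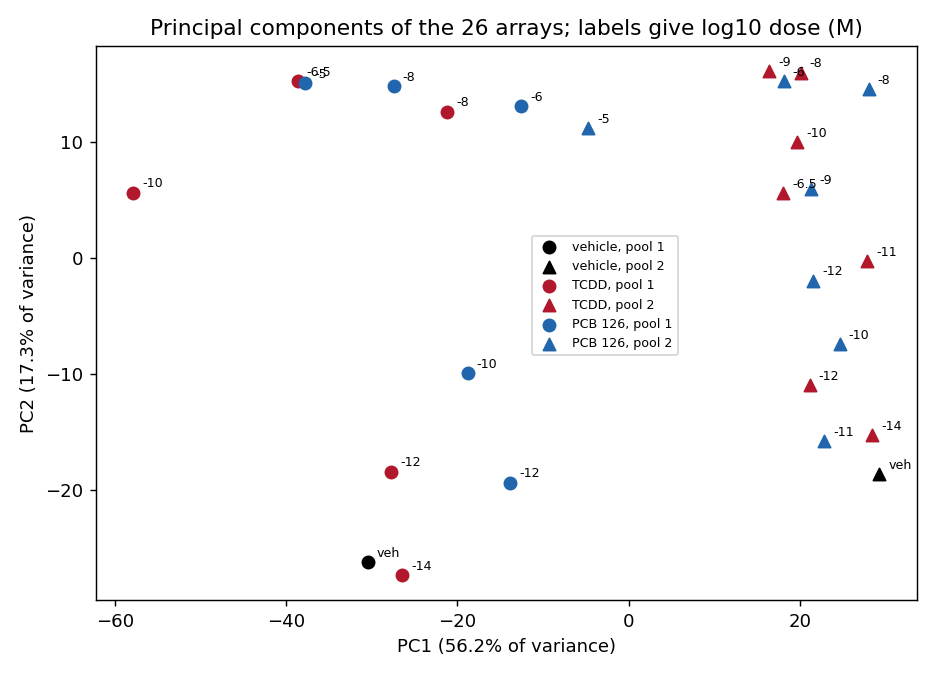
First and second principal components of the 26 arrays (56.2% and 17.3% of the variance), with 1 point per array labelled by its log10 dose in M, coloured by chemical and shaped by pool. The 11 arrays of pool 1 lie to the left of the 15 of pool 2, and 1 array of pool 2, PCB 126 at -5, lies between the pools.

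With increasing TCDD dose, 4 AhR targets had the steepest rises. Cyp1b1 rose by 1.08 ± 0.21 log2 per decade of dose (12 TCDD arrays), Cyp1a1 by 0.99 ± 0.21, Cyp1a2 by 0.96 ± 0.19, Aldh3a1, an aldehyde dehydrogenase, by 0.86 ± 0.17 and Nqo1, a quinone reductase, by 0.40 ± 0.08. Cyp2a1, a steroid-hydroxylating P450 of rat liver, rose by 0.72 ± 0.12 and the neutrophil chemokine Cxcl6 by 0.68 ± 0.13. Pla2r1, a receptor for secretory phospholipases, rose by 0.49 ± 0.11, and the phosphate cotransporter Slc17a1 and the steroid dehydrogenase Hsd17b2 each rose by 0.32 log2 per decade. Cyp2c12, the female-predominant P450 of rat liver, fell by 0.53 ± 0.10 log2 per decade and Sult1b1, a sulfotransferase acting on thyroid hormones, fell by 0.46 ± 0.08. The protease inhibitor Mug1 fell by 0.38 ± 0.10, the ethanol-oxidizing Cyp2e1 fell by 0.37 ± 0.06, and Cyp2c7 fell by 0.36 ± 0.06. Aldh1a1, which oxidizes retinaldehyde, fell by 0.29 ± 0.06, and Ugt2b, Cyp2c6v1, Cyp2d2 and the pyrimidine-degrading Upb1 fell by 0.28, 0.27, 0.25 and 0.24. These 20 genes had adjusted p values between 0.00305 and 0.0374 in limma and the same sign in both pools. In all, 161 of 5197 probe sets changed with TCDD dose, 85 up and 76 down, for 89 genes. Median centring of the arrays gave 69 up and 34 down, and without the pool term 39 probe sets were called. With only the TCDD arrays in the fit 46 were called, and 298 with vehicle placed 1 decade below the lowest dose. The count was 81 without the 316 nM array of pool 1, 257 without that of pool 2, 105 without the 10 nM array of pool 2, 12 with pool 2 alone and 0 with pool 1 alone.

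Among the 27 gene lists, the AhR battery shifted up with TCDD dose. Of its 7 measured members 5 rose, 0 fell and 2 did not pass, and 6 rose when adjusted over the list alone. The 2 others were Ugdh, which supplies the substrate of glucuronidation, with 0.05 ± 0.04 log2 per decade, and Nfe2l2, the transcription factor of the antioxidant response, with 0.09 ± 0.04. The list had a camera adjusted p of 6.8e-13, and adjusted p = 0.0224 with an estimated correlation.

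Of 12 measured UDP-glucuronosyltransferases and sulfotransferases, 4 fell with TCDD dose, 0 rose and 8 did not pass (5 fell adjusted over the list alone). The list had 25 genes. Ugt1a6, which is also in the AhR battery, was not analysed because its probe sets name several genes. Camera gave the list an adjusted p of 8.7e-05 downward, and adjusted p = 0.19 with an estimated correlation. Sult1b1 is given above, and Sult1a1, a phenol sulfotransferase, fell by 0.15 ± 0.03, Ugt2b35 fell by 0.16 ± 0.04 and Ugt2b1 fell by 0.08 ± 0.02, though Ugt2b1 was not called without the array labelled PCB 126 -12 of pool 2. Among 15 constitutive liver P450s, 5 fell and 2 rose (7 and 2 adjusted over the list alone). Cyp2a1 and Cyp2a2 rose, the latter by 0.23 ± 0.05, while Cyp2c6v1, Cyp2c7, Cyp2c12, Cyp2d2 and Cyp2e1 fell. This list shifted down with a camera adjusted p of 0.0125, 0.387 with an estimated correlation and 0.0631 with ranks, and was not called without the 0.01 pM array of pool 2 or the 10 nM array of pool 1.

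Acute phase and complement genes shifted up with TCDD dose (camera adjusted p = 0.00261, and adjusted p = 0.387 with an estimated correlation). Of 25 measured members, 3 rose, 2 fell and 20 did not pass, and 6 rose and 3 fell adjusted over the list alone. Cebpb, a transcription factor of the acute phase response, rose by 0.30 ± 0.05 log2 per decade, the endotoxin-binding protein Lbp by 0.22 ± 0.05 and the fibrinogen chain Fgg by 0.11 ± 0.03. Apcs, the serum amyloid P component, fell by 0.24 ± 0.06, and the protease inhibitor Serpina3c fell by 0.24 ± 0.06. Hepatocyte secreted and identity genes shifted down (camera adjusted p = 0.0125, 0.523 with an estimated correlation, 0.0525 with ranks and 0.104 with the mean of all probe sets per gene), and were not called without the 10 nM array of pool 1. Of 28 measured, 2 fell and 1 rose, with 12 lower and 1 higher adjusted over the list alone. Asgr2, a chain of the asialoglycoprotein receptor, fell by 0.14 ± 0.03 and Ambp fell by 0.13 ± 0.03, while Pon1, the paraoxonase of high-density lipoprotein, rose by 0.24 ± 0.05. In fry, the one-direction test gave adjusted p values of 0.0011 for the AhR battery, 0.00196 for the conjugation enzymes, 0.00803 for the P450s, 0.0591 for identity genes and 0.15 for acute phase genes.

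The other 22 lists were not called by camera in the TCDD trend, though some held single genes that passed. Camera called 10 lists without the 0.01 pM array of pool 1 and 3 without the 10 nM array of pool 1, against 5 with every array. Among amino acid breakdown and urea cycle genes (23 measured) 3 fell and 1 rose: Cps1, the entry step of the urea cycle, fell by 0.21 ± 0.05, Kynu of tryptophan breakdown fell by 0.22 ± 0.05, Arg1 fell by 0.17 ± 0.04, and Hal, which starts histidine breakdown, rose by 0.25 ± 0.06. Of the steroid and growth hormone axis (18 measured) 3 fell and 1 rose, namely Sult1a1, Sult1b1, Dio1 and Hsd17b2, and fry gave a one-direction adjusted p of 0.00303. The same fry test gave 0.00161 for glucose production and handling and 0.0318 for CAR and PXR targets, both downward. CAR and PXR targets (12 measured) had 3 lower genes, Cyp2b3, which fell by 0.20, Ephx1, which fell by 0.13, and Ugt2b1. Glucose production and handling (11 measured) had 1 gene up, Igfbp1 at 0.28 ± 0.05, and 1 down, the glucose transporter Slc2a2. In the NRF2 and glutathione list (20 measured) 2 fell, Gclc of glutathione synthesis and Akr7a3. The lists for bile acids (11 measured), retinoids (11) and cytoskeleton and dedifferentiation (24) each had 1 lower gene, Akr1d1, Aldh1a1 and Tpm1. No gene passed in limma for cholesterol synthesis (4 of 13 at an unadjusted p below 0.05), fatty acid synthesis (3 of 8), fatty acid oxidation and PPARa targets (3 of 20), cell cycle (1 of 11), ER stress (4 of 19), heat shock (1 of 12), p53 and apoptosis (1 of 14), ribosomal proteins (2 of 30), mitochondrial respiration (2 of 29) or clock genes (1 of 5). The median, mean and camera direction differed in sign for fatty acid oxidation, ER stress, p53, ribosomal proteins, clock genes, endothelial and stellate cell markers.

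Markers of other liver cell types were followed as well. Of 11 measured macrophage and Kupffer cell markers, the monocyte chemokine Ccl2 rose with TCDD dose by 0.29 ± 0.06 and the lysozyme Lyz2 fell by 0.19 ± 0.04 (list camera adjusted p = 0.283). No marker of endothelial cells (2 of 6 at an unadjusted p below 0.05), stellate cells and fibroblasts (1 of 13) or cholangiocytes (1 of 10) passed in limma.

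With increasing PCB 126 dose, Aldh3a1 rose by 0.89 ± 0.17 log2 per decade (12 PCB 126 arrays), Cyp1b1 by 0.86 ± 0.22, Cyp1a2 by 0.77 ± 0.19, Cyp2a1 by 0.67 ± 0.12 and Nqo1 by 0.33 ± 0.08. Cyp3a23-3a1, a P450 induced through the pregnane X receptor, rose by 0.58 ± 0.09, Hsd17b2 by 0.38 ± 0.09, the insulin-repressed binding protein Igfbp1 by 0.35 ± 0.06, and Slc17a1 and Pon1 by 0.30 each. Among the genes with the largest falls, the actin Acta1 fell by 0.63 ± 0.11, the actin-binding protein Tagln fell by 0.48 ± 0.09, and the myosin light chain Myl9 fell by 0.38 ± 0.07. Mug1 fell by 0.44 ± 0.10, A2m, an acute phase protein in rats, fell by 0.42 ± 0.10, and Serpina3c fell by 0.32 ± 0.06. Cyp2c12 fell by 0.39 ± 0.10, Cyp2c7 fell by 0.35 ± 0.07, and the secreted ribonuclease Rnase4 and Sult1b1 fell by 0.31 each. These 20 genes had adjusted p values between 0.00208 and 0.0371 and the same sign in both pools. In all, 221 of 5197 probe sets changed with PCB 126 dose, 81 up and 140 down, for 118 genes, and median centring gave 50 up and 163 down. Cyp1a1, with 0.73 ± 0.21 log2 per decade, did not pass (adjusted p = 0.0535), and without the array labelled PCB 126 -12 of pool 2 it rose by 0.87 ± 0.23 (adjusted p = 0.0339). Without that array the slopes of Cyp1b1, Aldh3a1 and Cyp1a2 were 1.11, 1.08 and 0.92. The count was 53 without the 1 pM array of pool 1, 371 without the 1000 nM array of pool 1, 134 without the 10 pM array, 113 without the 10000 nM array of pool 2, 110 with pool 2 alone, 0 with pool 1 alone and 56 without the pool term. It was 367 with only the PCB 126 arrays in the fit, 339 with vehicle placed 1 decade below the lowest dose, 69 without the highest dose, 104 on doses with both pools and 108 without 3 arrays that stood apart.

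The AhR battery was the 1 list that camera called in the PCB 126 trend (4 of 7 rose, 5 adjusted over the list alone, adjusted p = 1.13e-05, and adjusted p = 0.461 with an estimated correlation). Ugdh had 0.07 ± 0.04 log2 per decade and Nfe2l2 0.03 ± 0.04. Camera called 4 lists without the 0.01 pM TCDD array of pool 1, 3 without the 0.1 nM TCDD array of pool 1 or the 1 nM TCDD, 10 pM PCB 126 or 0.1 nM PCB 126 array of pool 2, and 2 without either vehicle array, the 1 pM TCDD array of pool 2 or the 10 nM, 1000 nM or 10000 nM PCB 126 array of pool 1. Constitutive P450s had 4 lower and 2 higher genes of 15 (5 and 2 adjusted over the list alone), with Cyp2c6v1 and Cyp2d2 falling by 0.24 and 0.25 and Cyp2a2 rising by 0.27. In the acute phase and complement list 3 genes fell, A2m, Serpina3c and Apcs, and Cebpb rose by 0.24 ± 0.05 (4 lower and 3 higher adjusted over the list alone, of 25). The median of this list was 0.02 and its mean -0.02. Cytoskeleton and dedifferentiation genes had 3 lower members, Myl9, the calpactin light chain S100a10 and Tpm1, and 1 higher, Anxa5 (7 and 1 adjusted over the list alone, of 24). Identity genes had 2 up, Pon1 and the apolipoprotein Apob at 0.26 ± 0.06, and 2 down, the coagulation factor F9 and Ambp (3 and 6 adjusted over the list alone, of 28; camera adjusted p = 0.0539). Among amino acid genes Hal rose by 0.30 ± 0.06 and Tat, the tyrosine aminotransferase, by 0.20 ± 0.04, while Kynu fell by 0.25 ± 0.05. CAR and PXR targets had Cyp3a23-3a1 up and Cyp2b3 and the efflux pump Abcb1b down. Lipid synthesis was represented by Dhcr7 and Fasn, which fell by 0.09 and 0.10, and bile acid transport by Abcc2, which rose by 0.11 ± 0.03. Single genes of the remaining lists were Slc37a4 (down) beside Igfbp1 (up) for glucose, Aldh1a1 (down) for retinoids, Sult1a1 and Sult1b1 (down) for conjugation, the stress gene Nupr1 (down), the clock gene Per2 (up) and Lyz2 (down, macrophages). Tagln fell among the stellate cell markers. Without the array labelled PCB 126 -12 of pool 2, Anxa5, Abcb1b, Dhcr7 and Slc37a4 were no longer called and Slc2a2 was called lower. The median, mean and camera direction differed in sign for CAR and PXR targets, fatty acid oxidation, retinoids, the steroid axis, acute phase genes, stellate cell and cholangiocyte markers.

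The slopes for TCDD and PCB 126 were set side by side over all 5197 probe sets. Of the probe sets called, 89 passed for both chemicals, 46 rising in both, 43 falling in both and 0 in opposite directions, against 1.32 and 2.05 for independent lists. They include probe sets of Cyp1a2, Cyp1b1, Aldh3a1, Nqo1, Cyp2a1, Cyp2a2, Igfbp1, Cebpb and Pon1 among the rising genes and of Cyp2c7, Cyp2c12, Sult1b1, Mug1, Aldh1a1 and Kynu among the falling ones. Slopes correlated across genes with Pearson r = 0.75 and Spearman rho = 0.39. Genes are not independent replicates, and no permutation p is given. Each slope was fitted within its own chemical, and the pool term was shared over all 26 arrays, which by design alone gives the 2 slope estimates a correlation of -0.000268. Across pools, r was 0.50 for TCDD in pool 1 against PCB 126 in pool 2 and 0.71 the other way round. Of 293 probe sets called for either chemical, 280 (95.6%) had the same sign. Of the 72 called for TCDD alone, 42 had an unadjusted p below 0.05 for PCB 126, and of the 132 called for PCB 126 alone, 65 had one for TCDD. The difference of the slopes was tested directly: limma called 0 probe sets, with 342 at an unadjusted p below 0.05 and a smallest adjusted p of 0.577. No gene was thus shown to change with one chemical and not with the other.

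**Figure D3:**
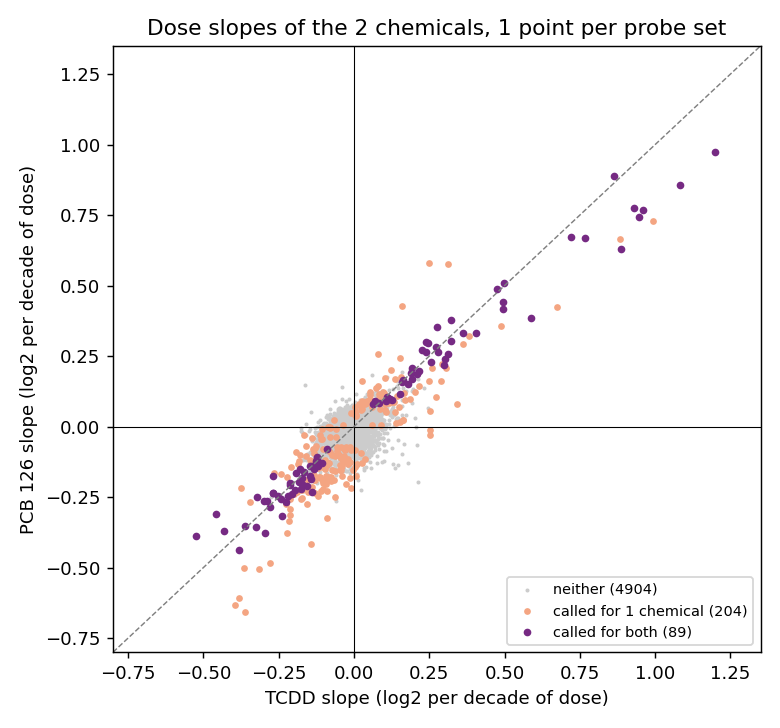
Slope with PCB 126 dose (vertical axis) against slope with TCDD dose (horizontal axis), both in log2 per decade, with 1 point per probe set and colours for probe sets called for neither, 1 or both chemicals. The 89 probe sets called for both lie in the upper right and lower left, and r over all 5197 is 0.75.

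At the upper end of the TCDD range (10 and 316 nM, 4 arrays) against vehicle (2 arrays), Cyp1a1 was at least 503-fold higher, a log2 difference of 8.97 ± 1.43. Cyp1a2 was at least 129-fold, Cyp2a1 at least 63.5-fold and Aldh3a1 at least 48.8-fold higher, and Cyp1b1 106-fold, Nqo1 8.06-fold and Cyp3a23-3a1 7.29-fold. Cxcl6 rose at least 21.8-fold, Pla2r1 at least 8.15-fold and Slc17a1 at least 4.97-fold. Folds written with at least are lower bounds, apart from their error, because the lower of the 2 signals lay under the array median in 1 or both pools, close to background. Sult1b1 was at least 9.28-fold lower (-3.21 ± 0.55 log2), Cyp2c12 9.1-fold, Acta1 6.9-fold, Cyp2c7 5.11-fold, Myl9 3.99-fold and Cyp2e1 3.8-fold lower. Serpina3c, Maob, an amine oxidase, Cyp2d2 and the sulfate transporter Slc26a1 fell by 1.88, 1.68, 1.62 and 1.56 log2. Adjusted p values of these 20 genes ran from 0.000681 to 0.049. Of 5197 probe sets, 70 were higher and 47 lower, for 63 genes, and 57 higher and 9 lower with each array centred on its median. Leaving out 1 vehicle array gave 55 (pool 1) or 52 (pool 2), leaving out the 316 nM array of pool 1 gave 61 and the 10 nM array of pool 2 gave 68, and 27 were called without the pool term. The highest dose alone gave 32, the lowest doses in place of vehicle 182, and a fit of only the arrays compared 27.

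By list, camera called 6 sets at the high TCDD doses, and 3 without the vehicle array of pool 1. The AhR battery had 5 of 7 members up (6 adjusted over the list alone, adjusted p = 4.53e-17, and adjusted p = 0.00873 with an estimated correlation), with 0.58 ± 0.28 log2 for Ugdh and 0.36 ± 0.25 for Nfe2l2. The measured conjugation enzymes, again without Ugt1a6, shifted down (2 of 12 fell, Sult1b1 and Sult1a1, 2 adjusted over the list alone). Camera gave them an adjusted p of 0.00307, and 0.283 with an estimated correlation. Constitutive P450s had 5 lower and 2 higher genes of 15 (6 and 2 adjusted over the list alone, adjusted p = 0.0136, and adjusted p = 0.33 with an estimated correlation). Acute phase genes shifted up (2 rose and 1 fell of 25, 7 and 3 adjusted over the list alone, adjusted p = 0.000905, and adjusted p = 0.33 with an estimated correlation), with Cebpb up by 1.85 ± 0.39 and Fgg by 0.90 ± 0.20. Identity genes shifted down (3 fell and 1 rose of 28, 4 and 1 adjusted over the list alone, adjusted p = 0.0382, adjusted p = 0.772 with an estimated correlation, 0.0801 with ranks, 0.0959 with the mean of all probe sets per gene, 0.0553 with each array centred on its median and 0.0759 without 3 arrays that stood apart): the apolipoproteins Apoa4 and Apoe fell by 1.17 and 0.46, Ambp fell by 0.93, and Pon1 rose by 1.72 ± 0.25. Cholesterol synthesis shifted up with 0 of 13 members past the limma threshold and 3 at an unadjusted p below 0.05, Sqle standing at 0.89 and Fdft1 at 0.51 log2 (adjusted p = 0.0136, 0.499 with an estimated correlation, 0.0707 with ranks and 0.1 without the pool term). Leaving out single arrays ended the call for conjugation enzymes (vehicle of pool 1), P450s (vehicle or 10 nM array of pool 1), cholesterol synthesis (vehicle of pool 2) and identity genes (either vehicle array, either 0.01 pM array, the 10 nM or 316 nM array of pool 1 or either 10000 nM PCB 126 array). Outside these lists Igfbp1 rose by 2.05, Hal by 1.99 and Tat by 1.24 log2. Of the macrophage markers, Ccl2 rose by 1.96 ± 0.32 and Lyz2 fell by 1.40 ± 0.30. In fry, the one-direction test gave adjusted p values of 0.000277 for the AhR battery, 0.0163 for conjugation enzymes and 0.0431 for P450s. It gave 0.16 for acute phase genes, 0.29 for identity genes and 0.29 for cholesterol synthesis. The mixed test of fry passed for lists that camera did not call, among them glucose handling (adjusted p = 2.5e-06), amino acid genes (3.5e-06) and CAR and PXR targets (8.7e-06).

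At the high PCB 126 doses (1000 and 10000 nM, 4 arrays) against vehicle (2 arrays), Cyp1a1 was at least 489-fold higher (8.93 ± 1.43 log2). Cyp1a2 was at least 188-fold, Cyp2a1 at least 99.9-fold and Aldh3a1 at least 72.2-fold higher, and Cyp1b1 75.1-fold and Nqo1 7.2-fold. Cyp3a23-3a1 rose 16.6-fold, Cxcl6 at least 13.9-fold, Pla2r1 at least 5.93-fold and Slc17a1 at least 5.3-fold, with the same vehicle signals as for TCDD. Acta1 was 13.5-fold lower (-3.75 ± 0.50 log2), Tagln 7.72-fold, A2m 6.26-fold, Myl9 5.92-fold, Sult1b1 5.9-fold and Cyp2c7 5.43-fold lower. Serpina3c, Slc26a1, Ugt2b and the aminopeptidase Aopep fell by 2.09, 1.90, 1.87 and 1.74 log2. Adjusted p values of these 20 genes ran from 0.00035 to 0.0452. In all 81 probe sets were higher and 77 lower, for 83 genes. The count of 158 became 81 or 80 without the vehicle array of pool 1 or pool 2, 100 without the 1000 nM array of pool 2 and 39 without the pool term.

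Camera called 2 lists at the high PCB 126 doses, and 1 without the 1000 nM or the 10000 nM array of pool 1. The AhR battery had 5 of 7 members up (5 adjusted over the list alone, adjusted p = 4.38e-14, and adjusted p = 0.0181 with an estimated correlation). Acute phase genes shifted up although 1 member rose, Cebpb by 1.72 ± 0.39, and 2 fell, A2m and Serpina3c, and were not called without the vehicle array of pool 2 or the 1000 nM or 10000 nM array of pool 1 (6 and 3 adjusted over the list alone, adjusted p = 0.0192, and adjusted p = 0.621 with an estimated correlation). Constitutive P450s had 3 lower and 2 higher of 15 (6 and 2 adjusted over the list alone). Among metabolic genes Hsd17b2 rose by 2.40 ± 0.51, Igfbp1 by 2.34 ± 0.40, Hal by 2.16 ± 0.29, Pon1 by 2.04 ± 0.25, Tat by 1.58 ± 0.20 and Apob by 0.95 ± 0.19, and Slc37a4 and Fasn fell by 1.02 and 0.96 log2. Ccl2, a macrophage marker, rose by 1.58 ± 0.32, and Tagln, a stellate cell marker, fell. Over the 4 comparisons, the camera calls that held with an estimated correlation were the AhR battery in the TCDD trend and at the high doses of both chemicals. No list's call turned direction with quantile normalization or median centring. Median, mean and camera direction differed in sign in 1 or both high-dose comparisons for the CAR, bile acid, NRF2, retinoid, ER stress, p53, ribosomal, clock, macrophage, endothelial and cholangiocyte lists, none of which was called.

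Each dose was also set against vehicle. For TCDD, limma called 0 probe sets at 0.01 pM (73 at an unadjusted p below 0.05) and at 1 pM (117), then 124 at 10 pM (39 up, 85 down), 64 at 0.1 nM (33 up, 31 down), 38 at 1 nM (30 up, 8 down), 110 at 10 nM (72 up, 38 down) and 32 at 316 nM (29 up, 3 down). For PCB 126 it called 0 at 1 pM (192 unadjusted), 10 pM (70), 0.1 nM (150) and 1 nM (200), then 73 at 10 nM (54 up, 19 down), 77 at 1000 nM (59 up, 18 down) and 156 at 10000 nM (67 up, 89 down). At 5% of 5197, 260 probe sets lie below an unadjusted p of 0.05 by chance. Without the array labelled PCB 126 -12 of pool 2, 10 probe sets were called at 0.1 nM PCB 126, 15 at 1 nM, 1 at 10 pM and 1 at 1 pM TCDD. Of the 85 lower calls at 10 pM TCDD, an array with the highest actin 3' minus 5' difference of pool 2 (2.19 log2), 7 were lower at another TCDD dose. Without the pool term, counts fell to 7 at 10 pM, 21 at 0.1 nM, 8 at 1 nM, 27 at 10 nM and 16 at 316 nM TCDD, and to 24, 25 and 36 at the 3 highest PCB 126 doses.

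**Figure D4:**
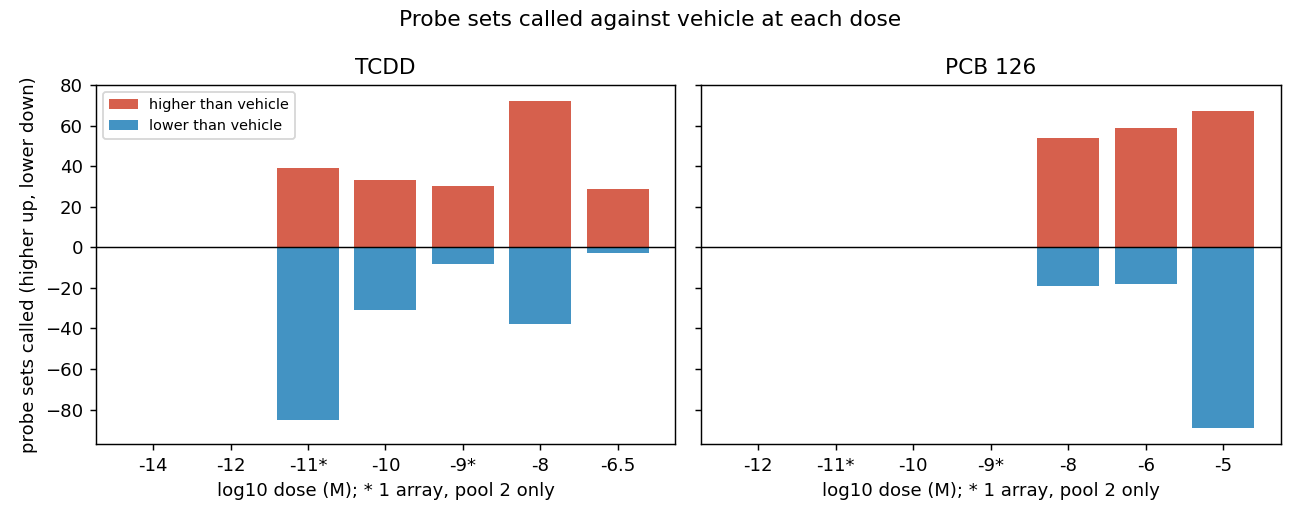
Number of probe sets called higher (above 0) and lower (below 0) than vehicle by limma (vertical axis) at each log10 dose in M (horizontal axis), for TCDD and PCB 126. With all 26 arrays, the lowest doses with calls were 10 pM TCDD (124, from 1 array) and 10 nM PCB 126 (73).

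The chemicals were compared at matched doses present in both pools. At 0.1 nM, Apob was 3.06-fold higher with TCDD than with PCB 126 (1.61 ± 0.22 log2, 95% interval 1.15 to 2.07, adjusted p = 0.0113), and A2m 7.25-fold lower (-2.86 ± 0.42 log2, -3.75 to -1.97, adjusted p = 0.0158). These were the 2 probe sets called, and 4 further probe sets of each gene were not called. The 0.1 nM TCDD array of pool 1 stood apart: it lay at -57.8 on the first principal component, where the next array lay at -38.6, and had the lowest upper quartile, 5.35 log2. For the AhR targets the differences at 0.1 nM were 5.68 ± 1.04 log2 for Cyp1b1 (3.44 to 7.91, adjusted p = 0.0718), 4.14 ± 0.82 for Aldh3a1 (2.38 to 5.90, adjusted p = 0.0785), 1.64 ± 0.43 for Nqo1 (0.71 to 2.57, adjusted p = 0.237), 1.99 ± 1.06 for Cyp1a2 (-0.30 to 4.28) and 1.23 ± 1.66 for Cyp1a1 (-2.41 to 4.87). Ugdh and Nfe2l2 had 0.14 and 0.05. Without the array labelled PCB 126 -12 of pool 2, Cyp1b1 was 51.1-fold higher with TCDD (5.68 ± 0.40, adjusted p = 2.54e-06), Aldh3a1 at least 17.6-fold (4.14 ± 0.52, adjusted p = 0.00162, with its PCB 126 signals under the array medians), and 7 probe sets were called. Among all probe sets 756 had an unadjusted p below 0.05, and the median difference over all probe sets moved from 0.01 to -0.10 log2 with median centring, which called 1 higher and 2 lower. The count of 2 was 0 without the pool term, 0 without the 0.1 nM TCDD array of pool 1, 885 without that of pool 2, 1 or 0 without the 0.1 nM PCB 126 array of pool 1 or pool 2, 6 without either 316 nM TCDD array, 7 without either 1 pM PCB 126 array and 4 without either 10000 nM PCB 126 array.

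At 10 nM the responses to TCDD and PCB 126 were not shown to differ. Cyp1a1 differed by 0.14 ± 1.66 log2 (95% interval -3.51 to 3.78), Cyp1a2 by -0.39 ± 1.06 (-2.68 to 1.90), Cyp1b1 by 0.51 ± 1.04 (-1.72 to 2.74), Aldh3a1 by -0.42 ± 0.82 (-2.19 to 1.34), Nqo1 by 0.15 ± 0.43 (-0.78 to 1.08), Ugdh by 0.01 (-0.63 to 0.65) and Nfe2l2 by -0.02 (-0.59 to 0.55). The array labelled PCB 126 -12 of pool 2 is not in this contrast but enters the shared spread. Without it the differences were 0.14 ± 0.53 for Cyp1a1, -0.39 ± 0.49 for Cyp1a2, 0.51 ± 0.40 for Cyp1b1, -0.42 ± 0.52 for Aldh3a1 and 0.15 ± 0.38 for Nqo1. With every array limma called 0 probe sets and 103 had an unadjusted p below 0.05. The count was 1 without the 10 nM TCDD array of either pool. At 1 pM, Cyp1a1 was higher with TCDD in pool 1 (6.21 log2) and lower in pool 2 (-1.43), with a mean difference of 2.39 ± 1.66 (-1.25 to 6.03). Cyp1b1 differed by -2.52 ± 1.04 (-4.75 to -0.29, adjusted p = 0.97), Aldh3a1 by -1.68 ± 0.82, Cyp1a2 by -0.93 ± 1.06, Nqo1 by -0.25 ± 0.43, Ugdh by 0.36 ± 0.29 and Nfe2l2 by 0.12 ± 0.26. Limma called 0 probe sets at 1 pM, with 101 at an unadjusted p below 0.05. Without the array labelled PCB 126 -12 of pool 2 the 1 call was Cyp1a1, higher with TCDD by 6.22 ± 0.66 log2 (adjusted p = 0.00119) against a single PCB 126 array whose signal lay under the array median, and 5 probe sets were called without the 1 pM PCB 126 array of pool 1.

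Between the upper ends of the dose ranges, which differ in molar dose, Cyp1a1 differed by 0.04 ± 1.17 log2 (TCDD minus PCB 126, 95% interval -2.54 to 2.62), Cyp1a2 by -0.55 ± 0.75 (-2.17 to 1.07), Cyp1b1 by 0.50 ± 0.73 (-1.08 to 2.08), Aldh3a1 by -0.56 ± 0.58 (-1.81 to 0.68) and Nqo1 by 0.16 ± 0.31 (-0.49 to 0.82). Limma called 0 probe sets, with 180 at an unadjusted p below 0.05, and 1 without the 10 nM TCDD array of pool 1. Fatty acid synthesis genes were higher with TCDD by camera (0 of 8 members past the limma threshold, 2 at an unadjusted p below 0.05, 1 adjusted over the list alone, adjusted p = 0.0266, and adjusted p = 0.671 with an estimated correlation). These intervals do not show that the chemicals act alike.

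Potency was compared through log-logistic dose-response curves. Cyp1a1 was induced with an EC50 of 0.316 pM TCDD (95% bootstrap interval 0.0251 to 2.24) and 3.55 pM PCB 126 (0.355 to 25.1), a potency of PCB 126 relative to TCDD of 0.0891 (0.00629 to 1.26). Without the array labelled PCB 126 -12 of pool 2 the EC50 values were 0.355 and 12.6 pM and the relative potency 0.0282 (0.0112 to 0.0708). Pool 1 alone gave 0.0141 (0.0126 to 0.0316). Pool 2 alone gave 1.26, with an interval from 0.0158 to 19.95 and its PCB 126 EC50 at the edge of the range searched. A curve fitted to linear instead of log2 values gave EC50 values of 17.8 and 199.5 pM, with a relative potency of 0.0891. On log2 values, relative potencies were 0.0562 for Cyp1a2 (0.0112 to 0.899), 0.0355 for Nqo1 (0.00891 to 0.178), 0.0158 for Aldh3a1 (0.00251 to 0.0891) and 0.0112 for Cyp1b1 (0.00158 to 0.0708). Cyp1b1 had EC50 values of 8.91 pM TCDD and 794 pM PCB 126, and Aldh3a1 15.8 and 1000 pM. With linear values the relative potencies became 0.0141 for Cyp1a2, 0.0158 for Nqo1, 0.0316 for Aldh3a1 and 0.0794 for Cyp1b1, whose TCDD EC50 became 112 pM. Over 35 of 50 genes that passed both trends and the limits on the curves, the median was 0.0398 (95% interval over genes 0.0281 to 0.0631). It was 0.0316 without the array labelled PCB 126 -12 of pool 2, 0.0708 in pool 1 alone, 0.0355 in pool 2 alone and 0.0596 with linear values. By point estimates TCDD was the more potent in 34 of the 35 genes, and Sult1b1, at 1.78, lay on the other side. Outside the AhR battery no intervals were computed per gene. The log10 relative potency of Sult1b1 was 0.25. Simulated curves with a maximum of 2 log2 and a residual SD of 0.3 had a median absolute error of 0.25. Genes this near to equal potency, Sult1b1 among them, were thus not shown to lie on either side. With pool 1 alone TCDD was the more potent in 32 of 38 genes (highest relative potency 22.4), and with pool 2 alone in 28 of 30 (highest 25.1). Genes are not independent replicates. Both EC50 values had to lie inside the tested doses, and these ranges are offset: -14 to -6.5 for TCDD and -12 to -5 for PCB 126 (log10 M). The tally and the median may in part reflect this offset, which was not tested. The simulated curves all held a true difference in potency, so they do not show how large that part is.

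**Figure D5:**
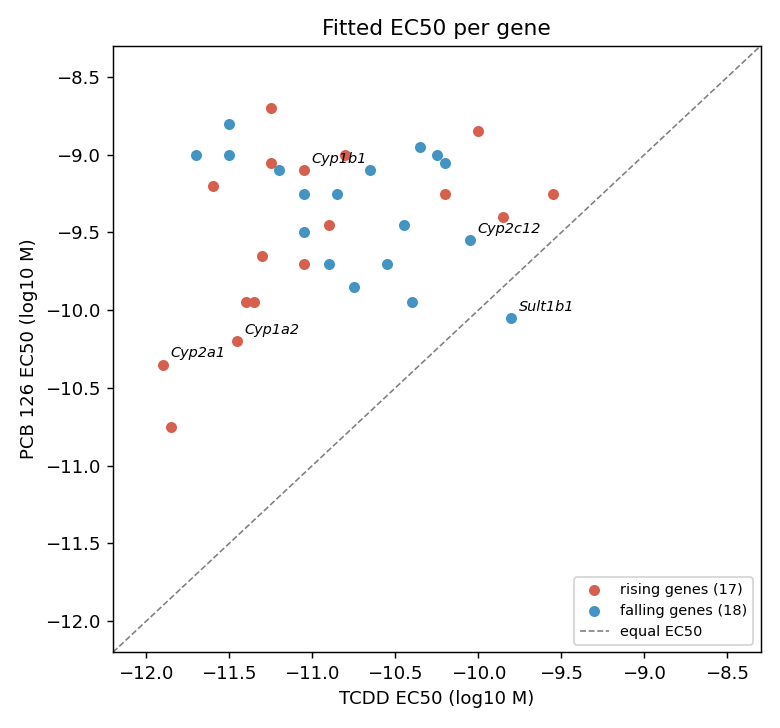
EC50 of PCB 126 (vertical axis) against EC50 of TCDD (horizontal axis), both as log10 M, with 1 point per gene for 35 genes, 17 rising and 18 falling with dose, and a diagonal of equal potency. All points but Sult1b1 lie above the diagonal, and the median relative potency is 0.0398.

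Finally, the slopes were compared between the pools. For TCDD, 3 probe sets differed, with 444 at an unadjusted p below 0.05, and for PCB 126 limma called 0, with 91 (1 call without the 0.01 pM TCDD array of pool 1 or the 10000 nM PCB 126 array of pool 2). For TCDD the count was 29 without the 1 pM array of pool 1, 11 without the 10 nM or the 316 nM array of pool 1, 7 without the 0.1 nM array of pool 1 or the 10 pM array, 6 without the 316 nM array of pool 2, 1 without the 0.01 pM array of pool 1, and 0 without the 0.01 pM or 1 pM array of pool 2 or the 1 nM PCB 126 array. Slopes with TCDD correlated across genes between pool 1 and pool 2 with r = 0.59, and slopes with PCB 126 with r = 0.74. Median-centred arrays gave 7 probe sets in place of 3.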

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

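The pool difference in the TCDD trend and the high-dose test of the PCB 126 -5 array were set out in advance. The tests of mixed-in pool 1 RNA and of raised background, and the 3 tests of the TCDD -11 array, were chosen only after the result was seen.

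Of the 5197 probe sets, 3 differed between the pools in their slope on TCDD dose by limma, a difference between groups of animals that the model tested directly. A probe set of Psmb3 had a slope of 0.26 log2 per decade in pool 1 and -0.02 in pool 2 (difference -0.28, adjusted p = 0.0291). A probe set of Gstp1 had 0.46 and 0.02 (-0.43, 0.0291), and a probe set of Stx8 0.18 and -0.04 (-0.21, 0.0385). None of the 3 was the probe set with the highest mean of its gene. That brighter probe set was not called for any of these genes. With 1 probe set per gene the count was 0, with the stricter filter 5, with arrays centred on their median 7 and with plain eBayes 9. Leaving out single arrays gave 29 calls (TCDD -12 of pool 1), 11 (TCDD -8 or -6.5 of pool 1), 7 (TCDD -10 of pool 1 or TCDD -11 of pool 2), 6 (TCDD -6.5 of pool 2), 1 (TCDD -14 of pool 1) or 0 (TCDD -14 or -12 of pool 2, or PCB 126 -9 of pool 2). A difference in biology between the 2 pools of 3 animals and a difference in handling cannot be told apart with 1 culture series per pool, and no test of either was run.

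The 6 reverse-strand control probe sets of rat actin and GAPDH, which the comparisons did not use, were 3.56 log2 higher on the PCB 126 -5 array of pool 2 than on the vehicle array of pool 2. On the first principal component the same array lay between the pools. Raised background is a candidate explanation: its mean reverse-strand signal of 8.36 log2 was above that of every other pool 2 array (highest 6.61, SD 0.64). The value lay within the range of the pool 1 arrays, 6.02 to 9.15. This signal therefore does not tell raised background from RNA of pool 1 mixed in. RNA of pool 1 mixed in stays open too, since bright probe sets had moved by a median share of 0.61 of the pool difference (95% interval 0.40 to 0.98, 58 probe sets) and dim ones by 0.45 (0.22 to 1.02, 17 probe sets), intervals that overlap. A response to the highest PCB 126 dose also stays open: the probe sets higher in pool 1 had risen from -6 to -5 by a median of 0.55 log2 in pool 1 (0.42 to 0.61, 75 probe sets) and 0.68 in pool 2. None of the 3 was excluded.

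At TCDD -11, an array of pool 2 alone, 85 probe sets were called lower than vehicle. A response to TCDD kept at higher doses is argued against: over the 4 higher doses of pool 2 the 85 had a median change from vehicle of -0.0674 log2 (95% interval -0.14 to 0.06), against -1.31 at -11. Calls alone decide little, with 7 of the 85 (8.24%) called lower at another TCDD dose and 0 in the TCDD trend, since few probe sets were called lower at the other doses. RNA quality of that array stays open as a candidate explanation, since its actin 3' minus 5' difference of 2.19 log2 was above the highest other of pool 2, 1.68, and the GAPDH difference was 1.24 against 0.73. A response to TCDD at that dose alone cannot be told apart from it, since no other array has the dose.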

How the results depend on the processing

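Named genes had 5182 values under alternatives set out in advance: 4667 had the same direction and call, 395 were no longer called, 120 became called and 0 turned direction. The removal of the PCB 126 -12 array of pool 2 or of 3 doubted arrays, curves on linear values, and median centring for lists were added after seeing the data. The 2 removals gave 980 gene values, 930 the same, 37 no longer called, 13 newly called and 0 turned. Leaving out each array and, in the trends, each pool gave 13196 gene values, with 631 no longer called, 120 newly called and 0 turned. For lists 517 of 540 values were the same under the alternatives set out in advance, 18 were no longer called and 5 newly called, and of 324 under the added ones 322 were the same and 2 no longer called. With 1 or 2 arrays per dose, the number of arrays limits precision, a lone array is assumed to vary like the other groups, and differences between dim signals are compressed. Unless stated, the cause of a change was not tested.

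Without the replicate block, the pool term, the TCDD trend had 39 calls, the PCB 126 trend 56, the high doses 27 (TCDD) and 39 (PCB 126), and the contrast of the chemicals at -10 had 0. By dose it gave 21 (TCDD -10), 7 (TCDD -11), 27 (TCDD -8), 16 (TCDD -6.5), 8 (TCDD -9), 24 (PCB 126 -8), 25 (PCB 126 -6) and 36 (PCB 126 -5). The pool difference then adds to the spread by construction. Of 168 named calls 51 were still called without it. With no filter, where more probe sets are tested, the pool difference had 7547 calls, the chemicals at -12 had 2, TCDD -12 had 1, TCDD -9 had 19 and PCB 126 -9 had 1. The stricter filter gave 2070, 12 for the chemicals at -10, and 5 for the pool difference in the TCDD trend. Median centring gave 103 (TCDD trend), 66 (TCDD high doses) and 7 (pool difference in the TCDD trend), and plain eBayes 9 for the last. With 1 probe set per gene, so fewer tests, counts were 91 (TCDD trend), 114 (PCB 126 trend), 2455 (pool difference), 63 and 82 (high doses), 8 (chemicals at -10) and 0 (pool difference in the TCDD trend).

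Without the PCB 126 -12 array of pool 2 there were 7 calls between the chemicals at -10, 1 at -12, and against vehicle 1 (TCDD -12), 10 (PCB 126 -10), 1 (PCB 126 -11) and 15 (PCB 126 -9). Without the 3 doubted arrays the PCB 126 trend had 108, the chemicals 9 at -10 and 1 at -12, TCDD -12 had 1, PCB 126 -10 had 7, PCB 126 -5 had 73 and PCB 126 -9 had 17. With only that chemical's arrays in the fit the trends had 46 (TCDD) and 367 (PCB 126) calls, and with vehicle placed 1 decade below the lowest dose 298 and 339. The PCB 126 trend had 69 without the highest dose and 104 on doses with both pools. The TCDD high doses had 32 with the highest dose alone, 182 against the lowest doses and 27 with only the arrays compared. The slope correlation was 0.39 by Spearman and 0.50 for TCDD of pool 1 against PCB 126 of pool 2. For lists, the estimated correlation gave 1 (TCDD trend), 0 (PCB 126 trend), 1 (TCDD high doses) and 1 (PCB 126 high doses), ranks 3 and 3 in the trends, and quantile normalization and the mean of all probe sets 2 each in the PCB 126 trend.

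Leaving out each array, and for trends and potencies each pool, gave ranges of 0 to 257 (TCDD trend), 0 to 371 (PCB 126 trend), 4060 to 4172 (pool difference), 52 to 165 and 80 to 180 (TCDD and PCB 126 high doses), 0 to 1 (chemicals at -8), 0 to 885 (at -10), 0 to 5 (at -12), 0 to 1 (between high doses), 0 to 29 and 0 to 1 (pool difference in the TCDD and PCB 126 trends), 3 to 10, 1 to 4, 3 to 6 and 1 to 3 (lists in the trends and high doses of TCDD and PCB 126 in turn: TCDD trend, PCB 126 trend, TCDD high doses, PCB 126 high doses), 0.0141 to 1.26 (Cyp1a1 potency) and 0.0355 to 0.0708 (median potency). It was not run for single doses.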

Other observations

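The genes in the next 2 paragraphs were chosen after their values were seen, as were the tests of the PCB 126 -12 array of pool 2 for a swapped label, a higher dose and a mixture. Its exchange test and the reordered doses and split arrays were set out in advance.

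At the high doses of both chemicals, single genes outside the lists changed by limma. Ahr, the receptor itself, rose by 1.22 ± 0.23 log2 with TCDD (adjusted p = 0.00856) and 0.89 ± 0.23 with PCB 126 (0.0452), and by 1.95 and 1.90 on a second probe set, while another had -0.08 with TCDD and was not called. Nrg1, a growth factor, rose with TCDD (1.44 ± 0.29, 0.0156) and with PCB 126 (1.499 ± 0.29, 0.00936), with 2 further probe sets called and 1 not. The phosphodiesterase Pde4b rose by 1.99 ± 0.27 (0.00106) and 2.20 ± 0.27 (0.000421) on 1 probe set. Of its 3 others, 1 was called, for PCB 126. Ier3 rose by 1.98 ± 0.43 (0.0229) and 2.05 ± 0.43 (0.0146), and Neurl3 by 1.18 ± 0.15 (0.000681) and 1.19 ± 0.15 (0.000476).

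Lcn2, a secreted lipocalin, rose by 0.85 ± 0.16 (0.00892) and 0.94 ± 0.16 (0.00312), the lysosomal protease Ctsl by 0.88 ± 0.12 (0.00115) and 0.85 ± 0.12 (0.000895), and Ctsc by 0.88 ± 0.20 (0.0286) and 0.97 ± 0.20 (0.0127), with its other probe set not called. Ankrd1 fell by 1.06 ± 0.23 (0.0258) and 1.54 ± 0.23 (0.00132), and Tsc22d1 by 0.98 ± 0.23 (0.0405) and 1.38 ± 0.23 (0.00308). Cited2 was not called with TCDD (0.0569) and fell by 1.69 ± 0.31 with PCB 126 (0.00595) on 1 of 3 probe sets. Each of these genes moved in its given direction in both pools.

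For the TCDD trend the limit of 5% was met only narrowly, and chance is not firmly excluded. Of 100 orders of the doses within pool and chemical, the real one included, 4 called as many as the real 161. The highest other called 271, and a share so near the limit is imprecise with 100 orders. For the PCB 126 trend the limit was met: 1 of 100 orders, the real one, called as many as 221, and the highest other called 7. That is the smallest share that 100 orders can give. For the pool difference 1 of 100 splits into 11 and 15 arrays, the real one, called as many as 4145, and the highest other called 3299. These splits treat single arrays as exchangeable. With 1 biological unit per pool they cannot test a difference between animals.

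The array labelled PCB 126 -12 of pool 2 had AhR targets well above those at the next higher dose, with shares of the full induction of 0.36 for Cyp1a1, 0.25 for Cyp1a2, 0.27 for Cyp1b1, 0.23 for Nqo1 and 0.23 for Aldh3a1. A label swapped with another array of pool 2 is argued against: 0 of the 14 swaps left the AhR targets without a fall of over 1 log2 between neighbouring doses. A higher dose than labelled stays open, since the distance to the line between neighbouring doses was 0.42 log2, within the 0.22 to 0.48 of 5 partly induced arrays. The 0.48 was that of TCDD -11, an array doubted for its RNA quality, and the highest of the others was 0.34 (TCDD -12). At a like Cyp1a1 share (0.37), PCB 126 -10 had shares of 0.0005 for Cyp1b1 and 0.004 for Aldh3a1. TCDD -11, with 0.35 for Cyp1a1, had 0.14 and 0.09. The distance test took the place of an earlier one on the spread of the shares (0.0863, interval 0.0414 to 0.170, against 0.105 for the narrowest partly induced array), which decided nothing. RNA or cells of an induced culture mixed in was not decided either: the array lay 0.26 log2 from a mixture with a share of 0.25 and 0.50 from the nearest single array. Of 8 other arrays, 5 also lay closer to a mixture than to any single array, but by smaller margins. The widest of these was 0.28 against 0.36 (TCDD -6.5), and TCDD -10 had 0.39 against 0.41. The count of arrays takes no account of these margins.

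Material exchanged with the TCDD -6.5 culture of pool 2, whose shares were low for its dose (0.68, 0.53, 0.66, 0.55 and 0.61), may explain both arrays, but their deviations over 608 probe sets with no dose trend correlated at 0.12, between the median of all pairs of pool 2 arrays (-0.04) and the 95th percentile (0.28), and this cannot be told apart from no exchange. No biological explanation was tested, since the design gives none for 1 array.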
